A study of Homo sapiens with 12 samples.

How the data were processed

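Total RNA from 12 samples of the human embryonic kidney line HEK293 was sequenced, in 2 experiments of 3 control and 3 RBFOX1 libraries each. RBFOX1 is a splicing factor that binds introns next to alternative exons. Per the labels, the inducible line descends from a clone deficient in RBFOX2, the paralog of RBFOX1, and carries a tagged mouse Rbfox1 transgene behind a promoter that doxycycline switches on. In experiment 1 the controls were untreated cells of this inducible line. In experiment 2 the controls were parental HEK293 cells given doxycycline. The RBFOX1 libraries of both experiments came from the inducible line after doxycycline, for which the labels state 0.5 µg/ml and 2 weeks. That protocol describes the inducible line and stands with all 12 samples, the untreated ones included, so the same dose and time were assumed for parental cells. The labels do not state whether the replicates of a group were separate cultures or inductions, so the p values measure only the spread between these samples, which may be technical. Libraries were made with an Illumina TruSeq RNA kit and sequenced from both ends on a NextSeq500. The labels give no kit for the removal of ribosomal RNA, no strand setting and no sequencing date.

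Per the submitters' processing notes, STAR 2.5.2b and the genome build GRCh37 (hg19) were used, without a stated role for either. For each experiment the authors deposited a gene table and a circular RNA (circRNA) table, both of raw counts: whole numbers, without normalization, whose totals differ between libraries. The circRNA tables count reads across back-splice junctions, where the end of an exon is joined to the start of the same or an earlier exon. Their columns have the layout that CIRCexplorer writes, but the caller is not named. Starts in these tables count from 0, and the positions printed here count from 1. The gene tables had 37184 entries in experiment 1 and 31910 in experiment 2. Of these, 23011 and 20675 carried a symbol, 11336 and 9029 were named from a table of gene identifiers, and 2837 and 2206 stayed without one. A RefSeq gene table for GRCh38.p14 gave gene types and the order of genes along chromosomes. Each column was matched to its sample by experiment, condition and replicate number.

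The comparisons, lists, alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise. Gene counts were filtered with filterByExpr (minimum count 10, minimum total 15) and scaled by TMM, and each experiment was tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided. Adjusted p is the Benjamini-Hochberg value over all features of a test, and a feature was called when it was under 0.05. CPM is the count scaled by the effective (TMM) library size in the usual way. The circRNAs with at least 10 reads over the 6 libraries and a read in at least 3 of them were tested the same way. Their library sizes were the effective sizes of the gene table, so that a global change of circRNA would stay visible. A further edgeR model took each circRNA and the gene count of its host in the same 6 libraries, as 12 columns with library as a block, and tested whether the circRNA changed differently from the host. The host count holds all reads of the gene, since the tables give no counts of linear junctions. Total circRNA was the sum of back-splice reads as CPM of the total gene counts, compared by a two-sided exact permutation test, for which 3 against 3 libraries allow no p under 0.1. For the size of circRNA and host changes, chosen after seeing the data, circRNAs of experiment 2 were also called without 1 library of each group and sized in those 2 libraries with a pseudocount of 0.5, and intervals came from a bootstrap over hosts. The difference between experiments was the interaction contrast over all 12 libraries in edgeR. The induced cells of the 2 experiments were also compared directly. Correlations and Fisher exact tests across genes or circRNAs describe these features, which are not independent replicates.

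Of 22 gene lists, those with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01. The test was repeated with an estimated correlation and with fry. The lists were the RBFOX family, genes with RBFOX-regulated exons, back-splicing regulators, circRNA turnover and export, mitochondrial genome-encoded genes, nuclear oxidative phosphorylation, the integrated stress response, mitochondrial chaperones and proteases, glycolysis, cholesterol synthesis, S phase, G2 and M phase, p53 targets, interferon-stimulated genes, neuronal and synaptic genes, extracellular matrix and adhesion, kidney epithelial genes, replication-dependent histones and cytosolic ribosomal proteins. Markers of haematopoietic cells, fibroblasts and hepatocytes were included as a check for other cells. GDF15 and SESN2 are in the stress and p53 lists, and ATP5C1, FN1, GRIN1, MBNL1, MBNL2, PTBP2, RBFOX2 and SNAP25 of the RBFOX exon list are each in 1 other list. Of the listed genes, 20 matched no entry. The list medians were the same with genes that had no reads in a group set at their bound. Named genes were the RBFOX family, the 5 called protein-coding genes with the largest rise and the 5 with the largest fall (mean log2 CPM of at least 1, all libraries of the groups apart), and the called member of each list with the largest rise and the largest fall. Named circRNAs were the 5 called ones with the largest rise and the 5 with the largest fall, or the 5 with the smallest unadjusted p where none was called, and the 3 with the highest mean count.

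Where a group had no read, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 reads the ratio is given with its 95% exact interval for counts. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. A count of 0 in 1 library allows up to 0.0556 to 0.0843 CPM in experiment 1 and 0.0596 to 0.08 CPM in experiment 2. Reads of near-identical genes, such as histones, ribosomal proteins and mitochondrial sequences copied in the nuclear genome, and of overlapping genes may be split or shared by the counting, and their values are uncertain to that extent. The replicate numbers were not taken as pairs in the main tests. After removal of group means, libraries with the same number correlated at 0.194, -0.11 and 0.0194 in experiment 1 and at 0.00479, 0.0296 and -0.0162 in experiment 2. With 3 libraries in a group, these low values do not exclude a pairing. No library was a copy of another of its group. The pipeline was tested on simulated data made from these tables. In experiment 1 it recovered 82.1% of 2-fold and 98.0% of 4-fold gene changes, and 66.3% of 4-fold and 88.5% of 16-fold circRNA changes. In experiment 2 it recovered 77.7% and 99.0% of these gene changes, and 30.9% and 79.2% of these circRNA changes. All shares on simulated data are of the changed features that passed the count filter there. A list raised 1.5-fold was called in both experiments. The simulated genes were drawn independently, so this does not show how the list test behaves when the genes of a list are correlated.

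Alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals alone, other count minimums, TMM over the circRNAs, limma on the log ratio of circRNA to host with a pseudocount of 0.5, a replicate block and leaving out each library. Counts and tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9. A planned search for the RBFOX motif in flanking introns was not run, since no genome sequence was used here. Some results that the naming rule covers are not reported.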

Results

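The series counted gene reads and back-splice reads in 12 libraries of HEK293 cells, 3 in each of 4 groups: uninduced and induced cells of an inducible RBFOX1 line (experiment 1), and doxycycline-treated parental cells and induced cells of that line (experiment 2). Total gene counts for replicates 1, 2 and 3 were 47821265, 48883252 and 34025315 in uninduced cells and 55298749, 42628237 and 45459845 in induced cells of experiment 1. They were 40809566, 44827245 and 50261916 in parental cells and 37826319, 37663525 and 38009529 in induced cells of experiment 2. Back-splice reads ranged from 10004 to 22661 per library in experiment 1 and from 18945 to 28691 in experiment 2. The mitochondrial ribosomal RNA MT-RNR2 took 23.1 ± 1.21% and 23.2 ± 1.06% of counts (SD, n = 3) in the uninduced and induced libraries of experiment 1, against 0.0300 ± 0.00127% and 0.0519 ± 0.0106% in the parental and induced libraries of experiment 2. Uninduced library 3 stood apart from the others of experiment 1, with the lowest depth, 1.68% of counts in the small RNA RN7SK and the lowest mean correlation with its own group (0.98986).

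Experiment 1 asks what follows in a single cell line when doxycycline switches RBFOX1 on. Every induced library had the drug and no uninduced one did, so doxycycline and RBFOX1 induction cannot be told apart in this experiment. RBFOX1 itself rose most, from 3.77 ± 0.584 to 39.2 ± 0.394 CPM (SD, n = 3), a log2 fold change of 3.37 (adjusted p = 6.63e-07). The transgene is of mouse origin, and these reads were counted under the human gene. RBFOX2, in which the labels call this line deficient, stood at 53.7 ± 3.90 and 53.7 ± 2.78 CPM, a log2 fold change of 0.0018 that was not called and turned to between -0.0357 and -0.0013 under some alternatives. Gene counts do not show whether these reads come from an intact or a deleted transcript. RBFOX3, the neuronal member of the family, fell by 0.78 on the log2 scale. Of 18978 genes tested, 1999 rose and 1972 fell, while 6622 had an unadjusted p under 0.05.

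After RBFOX1, the largest rises among protein-coding genes with a mean log2 CPM of at least 1 and the groups apart were in GARIN5A (log2 1.46), DNAH17 (1.39), a dynein chain of the sperm flagellum, INPP5D (1.34), the phosphoinositide phosphatase SHIP1, and GPATCH3 (1.18). DNAH17 went from 4.71 ± 0.489 to 12.4 ± 1.5 CPM (n = 3). The largest falls among these genes were in STRA6 (log2 -1.89), the cell-surface receptor for retinol transport, INHBE (-1.64), an activin subunit, ANKRD37 (-1.58), a target of hypoxia signalling, FUT1 (-1.52), the fucosyltransferase of the H antigen, and SCARA5 (-1.49), a ferritin receptor. INHBE went from 15.7 ± 0.841 to 5.02 ± 0.463 CPM and FUT1 from 21.4 ± 0.956 to 7.48 ± 0.486 CPM (n = 3). Genes without a matched gene type stood outside this ranking, among them NOV, chosen after its value was seen (log2 2.71).

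The integrated stress response, the programme that ATF4 drives when translation initiation is held back, fell together. Of its 31 genes 22 fell and 0 rose (25 fell adjusted over the list alone), with a median log2 fold change of -0.56. FGF21 fell by 1.60 on the log2 scale, ATF3 by 1.37, DDIT3 by 1.06 and GDF15 by 0.86, and ASNS, the asparagine synthetase, fell by 0.56. The list was called by camera (adjusted p = 7.05e-17), with adjusted p = 0.230 with an estimated correlation. Genes of extracellular matrix and adhesion fell in 10 of 28 cases (13 adjusted over the list alone), led by the collagen gene COL5A2 (-0.99), with a list median of -0.13 (adjusted p = 0.000237, and adjusted p = 0.266 with an estimated correlation). The neuronal and synaptic list fell, with 4 of 17 members lower (5 lower and 1 higher adjusted over the list alone) and a median of -0.22. MAP2, a microtubule protein of dendrites, went from 13.4 ± 0.803 to 6.5 ± 0.917 CPM (n = 3). This list's adjusted p was 0.0331, and adjusted p = 0.439 with an estimated correlation. Its call ended without uninduced library 1 (0.0554), uninduced library 2 (0.0641) or induced library 3 (0.0514). The kidney epithelial list fell with 3 of 12 members lower (3 adjusted over the list alone), among them CLDN3 (-1.54), KRT8 (-0.71) and CDH1 (-0.92), a median of -0.15 and adjusted p = 0.0295 (adjusted p = 0.267 with an estimated correlation); without induced library 2 its adjusted p was 0.0566. Fibroblast markers fell with 2 of 7 members lower (3 adjusted over the list alone), PDGFRA (-0.54) and COL1A1 (-0.52), a median of -0.37 and adjusted p = 0.0212 (adjusted p = 0.267 with an estimated correlation).

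Among the lists that rose, replication-dependent histones moved most, with 7 of 11 higher (11 adjusted over the list alone) and a median of 0.45. HIST1H3D went from 26.3 ± 4.06 to 58.7 ± 9.31 CPM (n = 3). The adjusted p of the list was 8.02e-06, and adjusted p = 0.439 with an estimated correlation. Cholesterol synthesis genes rose in 8 of 23 cases (8 adjusted over the list alone), among them SQLE (0.55), the squalene epoxidase, NSDHL (0.54) and LSS (0.50), with a median of 0.20 and adjusted p = 0.000966 (adjusted p = 0.439 with an estimated correlation). Factors of circRNA turnover and export rose in 6 of 18 cases, and 1 fell (9 and 1 adjusted over the list alone). POP1, a subunit of RNase P and MRP, rose by 0.48, and YTHDF2, a reader of methylated adenosine, by 0.45. The list median was 0.18 (adjusted p = 0.00302, and adjusted p = 0.230 with an estimated correlation). Nuclear oxidative phosphorylation rose, with 5 of 48 members higher (4 adjusted over the list alone), ATP5G1 (0.60) and ATP5J (0.54) among them, a median of 0.13 and adjusted p = 0.000337 (adjusted p = 0.591 with an estimated correlation, and 0.172 by fry). The mitochondrial genome-encoded list rose, with 3 of 13 members higher (3 adjusted over the list alone), MT-CYB (0.58), MT-ATP6 (0.48) and MT-CO3 (0.36), a median of 0.20 and adjusted p = 0.0056 (adjusted p = 0.439 with an estimated correlation, and 0.0504 by fry).

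The other lists of experiment 1 were not called, though single members were. Of the genes with RBFOX-regulated exons 5 of 23 rose and 4 fell (6 and 5 adjusted over the list alone), led by CLSTN1 (0.50) and the calcium channel gene CACNA1C (-0.60); the list's adjusted p was 0.959, its median was 0.018 and its mean -0.016. Back-splicing regulators had 7 of 25 higher, led by SRSF6 (0.43), and 5 lower, led by NOVA2 (-1.08), against 12 and 6 adjusted over the list alone (median 0.15, adjusted p = 0.0834). This list passed the threshold without uninduced library 3 (0.0251). Of the p53 targets 4 of 22 rose, led by TIGAR (0.62), and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.959), with a median of -0.00014 and a mean of 0.015. Of the interferon-stimulated genes 1 of 23 rose, ISG15 (1.00), and 4 fell, led by BST2 (-1.08), against 2 and 4 adjusted over the list alone (adjusted p = 0.701). In glycolysis 2 of 21 rose, led by ENO1 (0.52), and 4 fell, led by the glucose transporter gene SLC2A3 (-0.99), the same counts as adjusted over the list alone (adjusted p = 0.959, median 0.0085, mean -0.032). S phase genes had 3 of 25 higher, led by CDC6 (0.27), and 1 lower, RFC4 (-0.17), and G2 and M phase genes had 5 of 25 higher, led by PLK1 (0.48), and 1 lower, CDK1 (-0.17), the same counts as adjusted over the list alone (adjusted p = 0.134 and 0.113). The second of these lists passed the threshold without uninduced library 3 (0.0298) and by fry (0.0272). Mitochondrial chaperones and proteases had 2 of 13 higher, led by HSPE1 (0.26), and 1 adjusted over the list alone (adjusted p = 0.701). Ribosomal proteins had 1 of 45 higher, RPL11 (0.32), and 1 lower, and 0 adjusted over the list alone (adjusted p = 0.701). The RBFOX family had 1 higher and 1 lower of 3, also adjusted over the list alone (adjusted p = 0.455, and 0.000874 by fry). Of haematopoietic markers 2 were tested and 1 fell, VAV1 (-0.66), against 2 adjusted over the list alone, and of hepatocyte markers 1 was tested and 0 were called (log2 0.095).

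The size of this response depended on single libraries: 2104 genes were called without uninduced library 2, 1581 without induced library 1 and 1678 without induced library 3, against 5231 without uninduced library 3. Of the genes that the naming rule took, 13 lost their calls without induced library 1, at adjusted p of 0.0521 to 0.144, among them RBFOX3, ANKRD37, ATP5G1, HSPE1, ENO1, RFC4, CDK1, CLDN3, RPL11, VAV1 and PDGFRA. Part of these 13 also lost them without uninduced library 1 (5 genes, 0.0546 to 0.135), uninduced library 2 (6 genes, 0.0605 to 0.163), induced library 2 (4 genes, 0.0586 to 0.114) or induced library 3 (9 genes, 0.0534 to 0.167). The calls of RFC4 and CDK1 also ended with library totals (0.0557 and 0.0566), without the low-count filter (0.115 and 0.0817) and with the replicate number as a block (0.126 and 0.144), and DESeq2 gave CLDN3 no adjusted p.

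**Figure D1:**
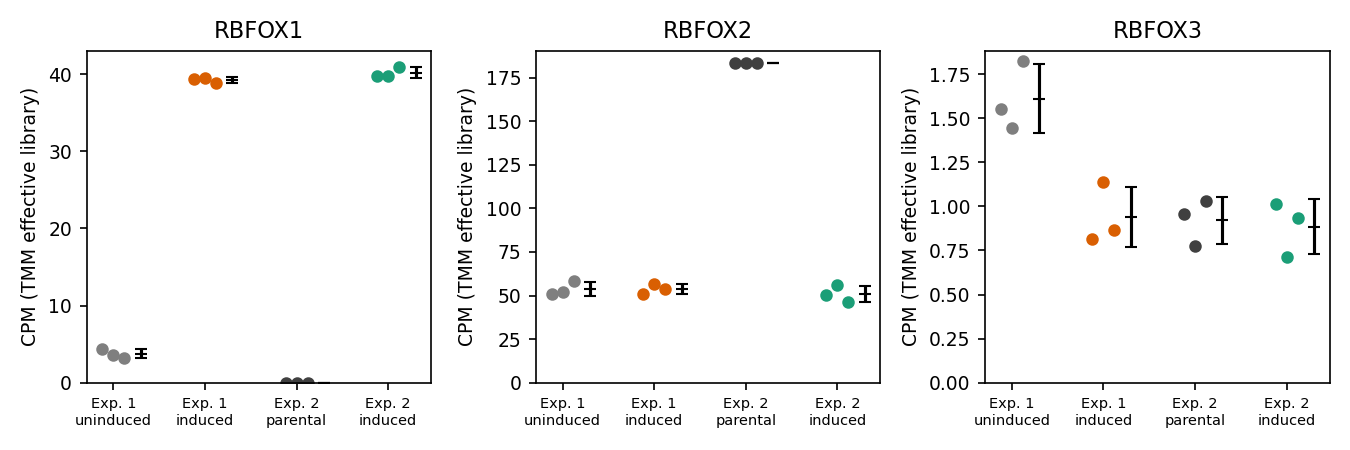
RBFOX1, RBFOX2 and RBFOX3 in CPM of the effective library, linear axes from 0, in the 4 groups; points are the 3 libraries of a group and the bar to their right is the mean ± SD. RBFOX1 stood at 39.2 and 40.2 CPM in the induced cells of both experiments, at 3.77 CPM in uninduced cells and at 0 in parental cells, and RBFOX2 at 183 CPM in parental cells and near 50.8 to 53.7 CPM in the other groups.

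The series asks whether RBFOX1 alters circRNA formation. In experiment 1 no circRNA was called. The table listed 29693 circRNAs, 29448 exonic and 245 intronic, of which 60.1% had 1 read in all. The 1701 tested came from 1140 host genes, with a median of 3 exons and 457 nt of spliced length. Of the 1701, edgeR called 0 (77 with an unadjusted p under 0.05) and DESeq2 called 0 (14 with an unadjusted p under 0.05). Against the host gene, edgeR called 0 of 1640 (76 with an unadjusted p under 0.05) and limma called 0 (87 with an unadjusted p under 0.05). On simulated data the circRNA test recovered 66.3% of 4-fold changes, and the test against the host 64.9%.

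The 3 most abundant circRNAs of experiment 1 gave values that did not pass the test. On GRCh37 these came from MAN1A2 (chromosome 1, 117944808 to 117963271; 369 and 415 reads in uninduced and induced cells), a Golgi mannosidase gene, CDYL (chromosome 6, 4891947 to 4892613, exon count 1; 303 and 309 reads) and DNAH14 (chromosome 1, 225140372 to 225161855; 261 and 248 reads). Their log2 fold changes were 0.040, -0.079 and -0.20, each with adjusted p = 0.965. The first turned to -0.097 without induced library 1. The second turned to 0.11 without uninduced library 1 and to 0.097 without induced library 2. The smallest unadjusted p values belonged to circRNAs of RP11-182I10.3 (13 reads in uninduced cells against 0 in induced cells), DMTF1 (0 against 12), AP4E1 (24 against 5), EIF4G3 (8 against 31) and ILKAP (1 against 12, a ratio of 11.1 with an interval of 1.64 to 473). In the order given, the adjusted p values of the edgeR test were 0.334, 0.557, 0.579, 0.965 and 0.965. Their host genes DMTF1, AP4E1 and ILKAP were not called, and EIF4G3 rose by 0.43.

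Total circRNA stood at 357 ± 55.8 CPM of gene counts in uninduced and 384 ± 23.7 in induced cells (SD, n = 3), a log2 difference of 0.11 ± 0.15 (SE) with a two-sided exact permutation p of 0.7. Uninduced library 3 held 294 CPM (95% interval 288 to 300), and without it the difference was -0.020. In experiment 2 the total was 585 ± 44.7 in parental and 548 ± 39.8 in induced cells (n = 3), a log2 difference of -0.094 ± 0.088 (exact permutation p = 0.5). Neither difference passed the exact test, whose smallest possible p is 0.1.

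**Figure D2:**
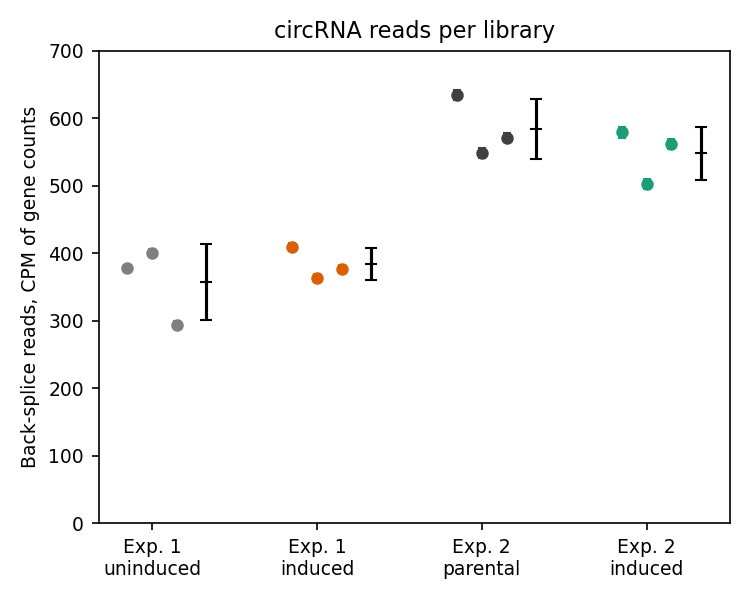
Back-splice reads as CPM of gene counts, linear axis from 0, for the 4 groups; points are libraries, with 95% counting intervals that lie mostly within the symbols, and the bar to their right is the mean ± SD of 3 libraries. The groups average 357 and 384 in experiment 1 and 585 and 548 in experiment 2, with the lowest library at 294.

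Experiment 2 sets the induced line against parental HEK293, both on doxycycline, with the dose and time of parental cells assumed, so its arms differ in RBFOX1, in RBFOX2 and in the clone. RBFOX1 had 0 reads in parental cells and 40.2 ± 0.704 CPM in induced cells (SD, n = 3), at least 1825-fold higher. RBFOX2 fell from 183 ± 0.0715 to 50.8 ± 4.76 CPM, a log2 fold change of -1.85 (adjusted p = 8.51e-17), and RBFOX3 was at 0.921 ± 0.134 and 0.886 ± 0.155 CPM, not called (log2 -0.059, which turned to 0.038 and 0.076 without parental library 3 and induced library 2). Of 17945 genes tested, 5765 rose and 5905 fell.

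Several of the largest changes were between silence and expression. With 0 reads in all parental libraries, MUC16, the mucin known as CA125, was at least 1127-fold higher at 24.8 ± 9.07 CPM (n = 3), the zinc finger gene ZNF677 at least 628-fold higher, CADPS, a priming factor of dense-core vesicles, at least 437-fold higher, and LHFPL4, a partner of inhibitory receptors, at least 337-fold higher. With 0 reads in all induced libraries, PABPC4L was at least 1743-fold lower, the steroid sulfatase gene STS at least 1469-fold lower, ZNF22 at least 1411-fold lower, the pseudouridine phosphatase gene PUDP at least 1126-fold lower and the neural transcription factor gene SOX11 at least 933-fold lower. SOX11 had stood at 24.7 ± 1.27 CPM in parental cells (n = 3).

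The p53 targets rose as a group in experiment 2, with 17 of 22 higher and 1 lower and a median log2 fold change of 1.01. GDF15 rose by 5.37 on the log2 scale, the death receptor gene FAS by 3.82, PHLDA3 by 3.18, the cyclin-dependent kinase inhibitor gene CDKN1A by 2.63 and MDM2, the p53 ubiquitin ligase, by 1.08, while TP53I3 fell by 1.51. The list was called by camera (adjusted p = 5.91e-07), with adjusted p = 0.520 with an estimated correlation. The integrated stress response rose, with 24 of 30 higher and 3 lower and a median of 0.60. NUPR1, a stress-induced chromatin protein, went from 0.212 ± 0.120 to 30.3 ± 1.66 CPM (n = 3), ALDH1L2 rose by 3.2, TRIB3 by 1.76, ASNS by 1.57 and DDIT3 by 1.21, while ATF3 fell by 0.69. Its adjusted p was 1.64e-06, and adjusted p = 0.520 with an estimated correlation. Nuclear oxidative phosphorylation fell, with 29 of 48 lower and 6 higher and a median of -0.20, from NDUFB9 (-1.23) of complex I and CYC1 (-0.96), the cytochrome c1 gene, to COX6B1, which rose by 1.46. Its adjusted p was 0.0149, and adjusted p = 0.831 with an estimated correlation. For each list of experiment 2, as many genes were called adjusted over the list alone as over all genes.

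The remaining 18 lists were not called by camera. Of these fry called 11, and the 7 it did not call were back-splicing regulators, mitochondrial genome-encoded genes, glycolysis, cholesterol synthesis, extracellular matrix and adhesion, kidney epithelial genes and histones. Genes with RBFOX-regulated exons had 12 of 23 higher, led by the synaptic fusion protein gene SNAP25 (2.97), and 7 lower, led by RBFOX2 (adjusted p = 0.438). Back-splicing regulators had 8 of 25 higher, led by PTBP2 (0.77), and 12 lower, led by NOVA2 (-1.88; adjusted p = 0.783). Factors of circRNA turnover and export had 4 of 18 higher, led by POP4 (1.21), and 12 lower, led by RPP25 (-3.29; median -0.26, adjusted p = 0.0925). Mitochondrial genome-encoded genes had 1 of 13 higher, MT-CO1 (0.60), and 7 lower, led by MT-ND6 (-1.24; adjusted p = 0.356). Mitochondrial chaperones and proteases had 2 of 13 higher, led by OMA1 (0.58), and 10 lower, led by HSPE1 (-0.53; adjusted p = 0.0925). In glycolysis 7 of 21 rose, led by GPI (1.63), and 8 fell, led by SLC2A3 (-1.44; adjusted p = 0.832). In cholesterol synthesis 7 of 23 rose and 12 fell, led by TM7SF2 (-1.18; adjusted p = 0.428). S phase genes had 13 of 25 higher, led by CCNE1 (0.84), and 8 lower, led by GINS2 (-0.89; adjusted p = 0.438), and G2 and M phase genes 14 of 25 higher, led by the proliferation marker MKI67 (1.21), and 7 lower, led by the spindle checkpoint kinase gene BUB1 (-1.23; adjusted p = 0.113). Ribosomal proteins had 23 of 45 higher, led by RPS16 (1.52), and 7 lower, led by RPL8 (-0.57; adjusted p = 0.0632). This list passed the threshold without parental library 1 (0.0149), induced library 1 (0.0487) or induced library 2 (0.0186), and with the replicate number as a block (0.0361).

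Interferon-stimulated genes had 9 of 24 higher, led by IFI44L (2.5), and 10 lower, led by the transcription factor gene IRF7 (-6.90; adjusted p = 0.783). Neuronal and synaptic genes had 10 of 21 higher, led by MAP2 (3.65), and 9 lower (adjusted p = 0.612). Of these, the neurofilament gene NEFM fell by 6.15. The median of this list was -0.021, its mean -0.30 and the direction of its test positive. Extracellular matrix and adhesion had 14 of 30 higher, led by LAMA4 (2.07), and 13 lower, led by SPARC (-9.41), which went from 86.2 ± 3.74 to 0.124 ± 0.0936 CPM (n = 3); the list's adjusted p was 0.926, its median 0.049 and its mean -0.35. Kidney epithelial genes had 2 of 11 higher, led by EPCAM (3.38), and 6 lower, among them CDH6, with 50 reads against 2, a ratio of 20.7 with an interval of 5.44 to 176 (adjusted p of the list = 0.612). Replication-dependent histones had 2 of 11 higher, led by HIST1H3D (5.73), and 5 lower, led by HIST1H1D (-1.47; adjusted p = 0.473, median -0.11, mean 0.20). Fibroblast markers had 1 of 7 higher, LOX (0.73), and 4 lower, led by the collagen gene COL3A1 (-4.31; adjusted p = 0.404). Haematopoietic markers had 2 of 4 lower (adjusted p = 0.473), and of hepatocyte markers 0 were tested. The RBFOX family had 1 higher and 1 lower of 3 (adjusted p = 0.926), with a median of -0.059 and a mean above 0.

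**Figure D3:**
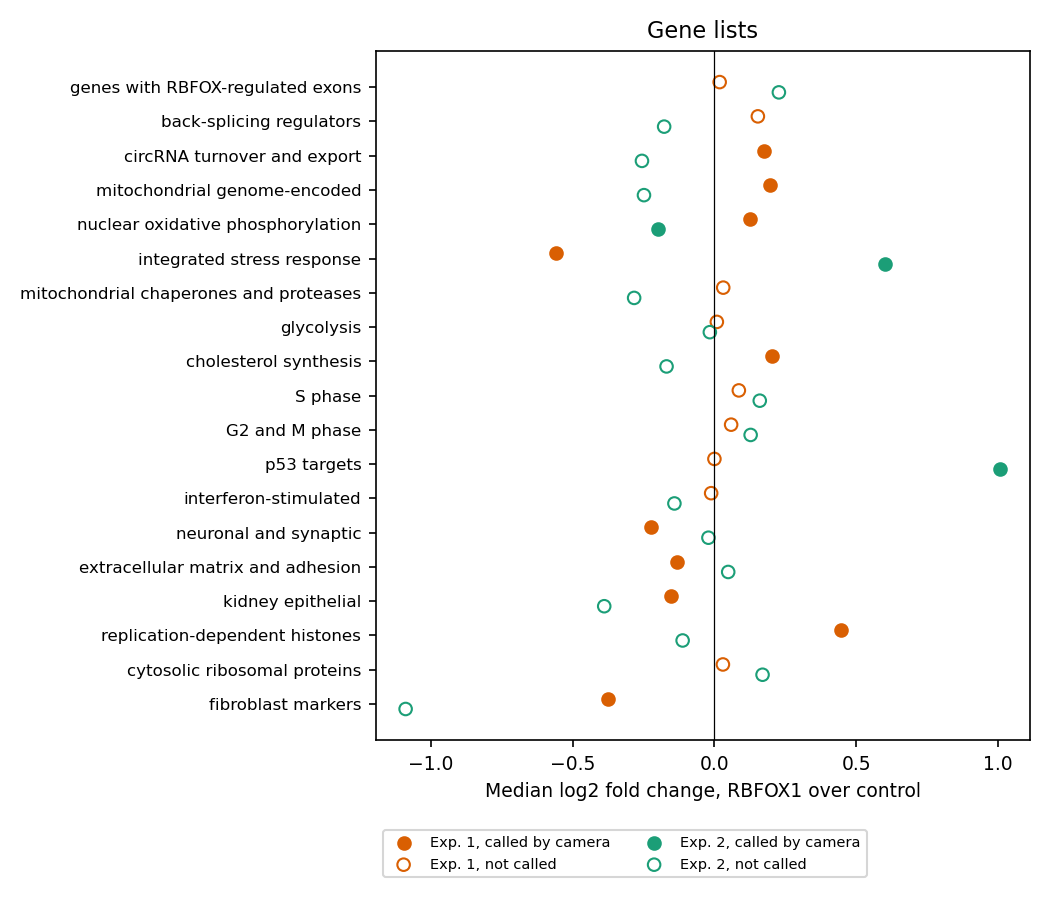
Median log2 fold change of the tested members of each list with at least 3 tested in both experiments, except the RBFOX family, RBFOX1 over control, in experiment 1 (orange) and experiment 2 (green); filled points are lists called by camera with the preset correlation and open points are not called. The integrated stress response lies at -0.56 in experiment 1 and 0.60 in experiment 2, and p53 targets at 1.01 in experiment 2; no list was called in either experiment with an estimated correlation.

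In experiment 2, 40 of 2381 tested circRNAs were called, 17 higher and 23 lower in induced cells. The strongest rise was in circRNAs of ERC1, a scaffold protein gene of presynaptic active zones, that share a start at position 1345935 of chromosome 12 (GRCh37). The circRNAs ending at 1399178, 1481143 and 1553916 had 0 reads in parental cells and 441, 152 and 26 reads in induced cells, at least 177-fold, 61.1-fold and 10.5-fold higher. The first of them, of 3 exons, stood at 3.90 ± 0.340 CPM in induced cells (n = 3; adjusted p = 1.97e-90). The ERC1 gene count rose by 0.41 on the log2 scale. A circRNA of the inositol trisphosphate receptor gene ITPR2 (chromosome 12, 26703180 to 26755639) had 0 against 22 reads, at least 8.85-fold higher. A circRNA of AFF2 (chromosome X, 147743429 to 147744289) went from 4 to 77 reads (log2 4.4), and the AFF2 gene rose by 3.74.

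The falls that the naming rule took included a pair of circRNAs of the ubiquitin ligase gene MID1 (chromosome X, 10491132 to 10535643, with 81 reads against 0, at least 22.4-fold lower, and 10534928 to 10535643, with 76 against 3, a ratio of 21.0 with an interval of 6.92 to 104), and the MID1 gene fell by 2.21. The circRNA of the sodium-calcium exchanger gene SLC8A1 (chromosome 2, 40655613 to 40657444) had 55 reads against 0, at least 15.2-fold lower, and its gene fell by 8.38. Circular RNAs of the mitochondrial carrier gene SLC25A32 (chromosome 8, 104417004 to 104420012; 26 reads against 0, at least 7.18-fold lower) and of WSCD1 (chromosome 17, 5983691 to 5998543; 40 against 2, a ratio of 16.6 with an interval of 4.30 to 142) also fell. Among the most abundant, SPECC1 (chromosome 17, 20107646 to 20109225) fell from 4.25 ± 0.247 to 1.60 ± 0.258 CPM (n = 3; log2 -1.41). CDYL (1092 against 689 reads, log2 -0.40, adjusted p = 0.120) and DEK (chromosome 6, 18236683 to 18258636; 300 against 339 reads, log2 0.44, adjusted p = 0.290) were not called by edgeR. DESeq2 (adjusted p = 0.0292) and edgeR with at least 30 reads (0.0376) did call CDYL.

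Measured against their host genes, 2 of 2290 circRNAs were called by edgeR, both of ERC1 and both higher: the one ending at 1399178 (adjusted p = 0.000116) and the one ending at 1481143 (adjusted p = 0.00174). With parental cells at the floor of 3 counts, they exceeded the change of the host by at least 7.06 and 5.52 on the log2 scale. Both edgeR calls ended when any 1 of the 3 induced libraries was left out. On the log ratio of circRNA to host, limma called 3 circRNAs, these 2 and 1 that was lower. In the circRNA test itself, 23 were called without parental library 1, 26 without parental library 3 and 14 without induced library 1. WSCD1 lost its call without parental library 1 (adjusted p = 0.0709) or induced library 1 (0.0936), and SLC25A32 without induced library 1 (0.0658). On simulated data the circRNA test of this experiment recovered 30.9% of 4-fold changes, and the test against the host 6.15%.

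The experiments were also set side by side. In their induced cells RBFOX1 stood at 39.2 and 40.2 CPM when each experiment was scaled alone, and at log2 -0.20 for experiment 2 against experiment 1 when they were scaled together (adjusted p = 0.00209). The 17084 genes tested in both did not move together: across genes, log2 fold changes correlated at r = -0.025 and rho = -0.084. Of 2768 genes called in both, 1066 (38.5%) had the same sign. The genes higher in both numbered 590, against 658 if the calls were independent, and those lower in both 476 against 591. Higher in experiment 1 and lower in experiment 2 were 834 against 630, and the reverse 868 against 618 (Fisher exact p = 1.02e-24 and 3.33e-37). These p values treat genes as independent and do not measure the spread between libraries. MAP2, GDF15 and HSPE1 were called in opposite directions, and SLC2A3, NOVA2 and HIST1H3D in the same direction. The effects differed by the interaction test for 10401 of 19942 genes and 7 of 4149 circRNAs. On simulated data this test recovered 69.2% of 2-fold gene changes, but 7.14% of 4-fold and 38.5% of 16-fold circRNA changes. The 2 counts therefore do not compare how often genes and circRNAs differed.

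For circRNAs, 12447 were listed in both experiments and 1163 tested in both, with r = -0.027 and rho = -0.055 between their log2 fold changes. Of the 40 called in experiment 2, 31 were tested in experiment 1 and 16 of these had the same sign there, 0 of them with an unadjusted p under 0.05. The circRNA of MND1 had the opposite sign (log2 1.42 against -2.59) with an unadjusted edgeR p of 0.0346 in experiment 1. The 3 ERC1 circRNAs without parental reads had 57 reads in uninduced and 81 in induced cells of experiment 1. The induced cells of the 2 experiments, alike in line and treatment, differed in 13494 of 18288 genes. These libraries also differed in MT-RNR2, at 23.2% and 0.0519% of counts, though the labels name 1 kit for both experiments.

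**Figure D4:**
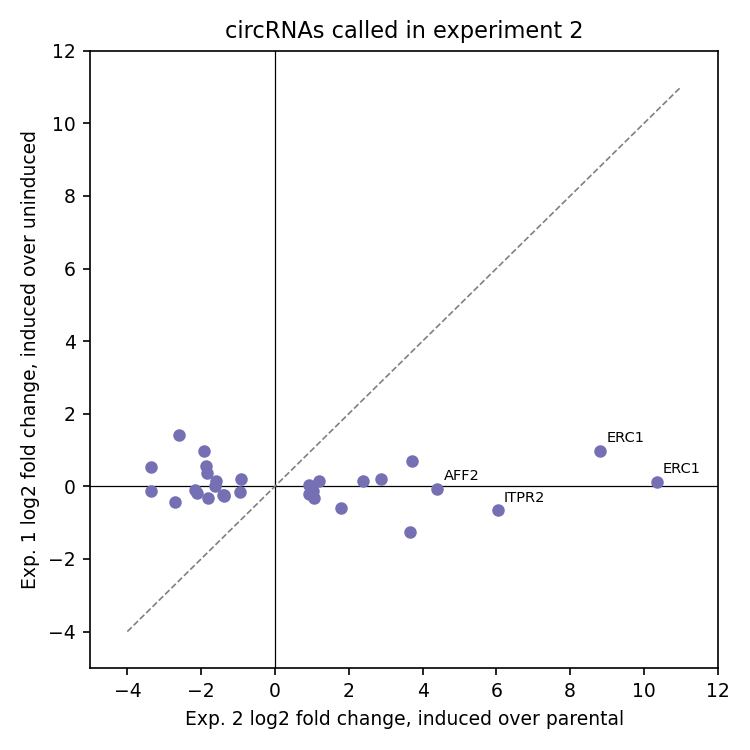
Log2 fold change of the circRNAs called in experiment 2 (horizontal axis) against that of the same circRNAs in experiment 1 (vertical axis), for the 31 tested in both; the dashed line marks equal values and the ERC1, ITPR2 and AFF2 circRNAs are named, of which ERC1 and ITPR2 had 0 parental reads and a horizontal position that depends on the prior count. Points spread along the horizontal axis and lie between -1.26 (COL25A1) and 1.42 (MND1) on the vertical axis, with 16 of 31 on the same side in both experiments.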

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

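The tests of single explanations in this part were chosen after the results were seen; the counts of other groupings of the libraries were planned. The results here were singled out because an effect differed between the experiments by the interaction test, written as experiment 1 minus experiment 2. This held for 10401 genes and 7 circRNAs.

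Among genes, the fitted log2 differences with the largest positive values were 16.48 for ENSG00000182572, 14.73 for GYG2, the glycogenin gene, and 13.54 for ENSG00000256316, all with at least 962 reads in each parental library and 0 or 1 in every other library. In experiment 1 these 3 genes were at or under the floor in both arms, so the size of each difference depends on the prior count and on single reads. The call of ENSG00000256316 ended without induced library 1 of experiment 1 (adjusted p = 1.00) and that of GYG2 without its induced library 2 (1.00). The largest negative ones were -12.63 for MUC16, -12.61 for LINC02226 and -12.17 for ZNF677, each with 0 reads in parental cells and at least 290 in each library of experiment 1. With parental cells at the floor of 3 counts, these 3 become -9.79, -9.78 and -9.34, and the fitted values depend on the prior count. Of the genes named in both experiments, the difference was -10.3 for RBFOX1, -6.23 for GDF15, -4.70 for MAP2, -4.58 for HIST1H3D, 1.85 for RBFOX2, 0.79 for HSPE1 and 0.45 for SLC2A3, where that of RBFOX1, without parental reads, is -7.46 at the floor. Of the circRNAs, it was -10.19 and -7.79 for those of ERC1 ending at 1399178 and 1481143 (-7.35 and -4.95 at the floor), -4.46 for AFF2, 3.24 for SNX25 (chromosome 4, 186168448 to 186188309) and 1.62 for RNF138 (chromosome 18, 29691717 to 29693823). The call of SNX25 ended without parental library 1 (0.0926) or induced library 1 of experiment 2 (0.0642), and that of RNF138 without its induced library 2 (0.0588) or 3 (0.0679).

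Of 21 lists, 7 differed by camera, a test chosen after seeing the data. The median differences were -1.10 for the integrated stress response, -1.01 for p53 targets, 0.57 for replication-dependent histones, 0.53 for cholesterol synthesis, 0.48 for mitochondrial genome-encoded genes, 0.43 for circRNA turnover and export and 0.32 for nuclear oxidative phosphorylation. With an estimated correlation 0 lists were called, with adjusted p of 0.0715 for the integrated stress response, 0.079 for p53 targets and for circRNA turnover, and 0.765 for the others.

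The first pattern is that 40 circRNAs were called in experiment 2 and 0 in experiment 1 (edgeR, with 284 and 77 at an unadjusted p under 0.05, and 0 in experiment 1 by DESeq2). A rise of RBFOX1 above its uninduced level is argued against as the cause by the cells of experiment 1. There the called circRNAs had a median log2 fold change of 0.0395 in the direction of experiment 2 (bootstrap interval -0.198 to 0.153). Their median in experiment 2 was 1.88. The 3 ERC1 circRNAs without parental reads had 57 reads in uninduced and 81 in induced cells of experiment 1. The 57 reads do not decide by themselves, since uninduced cells already held 3.77 CPM of RBFOX1. Of the 35 other than ERC1 with a host in the test, 33 (94.3%) had a host called in the same direction, against 47.8% of the other circRNAs (Fisher exact p = 7.99e-09), and across 2287 circRNAs the changes of circRNA and host correlated at rho = 0.354 (permutation p = 1e-04, the smallest possible), against 0.0789 in experiment 1 (interval 0.0281 to 0.125, permutation p = 0.0011), too close to the bound of 0.1 to tell a relation of that size from a weaker one. So a change of the host is a candidate explanation for the direction of these 35, but it is argued against for the full size. In libraries left out of the call, 25 circRNAs, 21 of them among the 35, gave a median excess over the host of 0.684 on the log2 scale (interval 0.397 to 1.22). This median runs over all pairs of left-out libraries with a call, so a circRNA called in several pairs counts more than once. Most of these sizes come from pairs with induced library 2. The interval is a bootstrap over hosts and does not measure the spread between libraries. By edgeR 0 of the 35 were called against their host, but on simulated data that test recovered only 6.15% of 4-fold changes, so this does not decide. For ERC1 the host is argued against, as the circRNA exceeded it by at least 7.06 on the log2 scale. For all of them the lower RBFOX2 (50.8 against 183 CPM), a response already complete at the 3.77 CPM of RBFOX1 in uninduced cells and other differences of the clone stay open, untested. The ERC1 circRNAs ending at 1399178 and 1481143 had 53 and 24 reads in induced cells of experiment 1, against 441 and 152 in those of experiment 2. Features that the 2 sets of induced cells share do not account for this gap.

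The second pattern is that the integrated stress response fell in experiment 1 and rose in experiment 2. Uninduced library 3 as the cause of the fall is argued against, since without it the median was -0.5115 and the list stayed called. So is RBFOX1 as the sole cause in both with an effect in 1 direction, since the medians had opposite signs and differed by -1.099. RBFOX1 in induced cells was at log2 -0.20 for experiment 2 against experiment 1. The starting levels differed, at 3.77 CPM in uninduced and 0 in parental cells, so an opposite effect of the lower level stays open. With an estimated correlation the camera calls in experiment 1, in experiment 2 and of the difference ended (adjusted p = 0.230, 0.520 and 0.0715). For the rise (0.5999) doxycycline cannot be told apart from the other differences of the arms, because both received it but an equal dose and time rests on a protocol written for the inducible line. For the fall (-0.5589) doxycycline and RBFOX1 induction cannot be told apart, because every induced library of experiment 1 had the drug and no uninduced one did. The clone, for the rise, and the difference between the 2 sets of samples that share a line and a treatment stay open.

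How often other groupings of the same libraries gave as many calls was counted next. With 3 libraries against 3 there are 10 groupings, too few for a share under 0.05. In experiment 1 the real grouping called 3971 genes and no other called any (1 of 10 as large), and it called 10 lists against at most 8 (1 of 10). For circRNAs, with or without the host, the real grouping and each other one called 0 (10 of 10). In experiment 2 the real grouping called 11670 genes against at most 0 (1 of 10), 40 circRNAs against at most 1 (1 of 10), 2 circRNAs against their host against at most 0 (1 of 10), and 3 lists against at most 6 (7 of 10). For the induced cells it was 13494 genes against at most 0 (1 of 10). For the difference between experiments 24 groupings were drawn. For genes 1 of 24, the real one, reached 10401 and the highest other was 9513, a share under the planned 0.05. Only 3 of the other groupings kept the arms of experiment 2, and they gave 7611, 8714 and 9513 genes. The rest mixed those arms, which removes most of the contrast, so their low counts were set in advance. These draws therefore cannot exclude chance for a difference between experiments. Chance was not excluded for circRNAs either, where 4 of 24 reached 7 and the highest other gave 13. The 3 others among these 4 all left the arms of experiment 2 as they were and regrouped only experiment 1. They gave 7611 to 9513 genes, so the arms of experiment 2 gave large counts even with experiment 1 regrouped. Without them the highest counts were 3 genes and 0 circRNAs, which mixing those arms set in advance. The draws therefore do not show what experiment 1 adds.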

How the results depend on the processing

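The alternatives were chosen before the data were examined, except the test of lists between experiments and leaving out libraries for the agreement of the experiments and for the induced cells, which were chosen after seeing the data. The numbers of called genes of experiment 2 (11036 to 11394 with 1 library left out), of induced cells (12907 to 13540) and of genes whose effect differed between experiments (9620 to 10564) stayed within 1.5 times the value reported under each alternative. The 0 calls among circRNAs of experiment 1 stayed 0 in edgeR and DESeq2, and those against the host gene stayed 0 in edgeR and limma. Both also stayed 0 in edgeR with 1 library left out (0 to 0) and with every count minimum tried.

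In experiment 1, 2327 genes were called with the replicate number as a block (2312 of them among the 3971), a pairing that the correlations neither bear out nor exclude. With 1 library left out, 1581 to 5231 genes were called. In experiment 2, 14 to 41 circRNAs and 0 to 2 circRNAs against their host were called with 1 library left out. Lists called by camera numbered 9 to 12 in experiment 1, 3 to 4 in experiment 2 and 5 to 8 for the difference between experiments with 1 library left out. With an estimated correlation 0, 0 and 0 were called, and fry called 10 in experiment 1, 8 of them among the 10 reported and without the mitochondrial genome-encoded (adjusted p = 0.0504) and nuclear oxidative phosphorylation (0.172) lists, and 14 in experiment 2, the 3 reported among them. The circRNAs that differed between experiments numbered 6 to 8 with 1 library left out and 23 with at least 60 reads, where 496 were tested in place of 4149 and fewer tests were adjusted for. The share of doubly called genes with the same sign ran from 35.5% to 41.8%. Total circRNA ran from -0.020 to 0.20 on the log2 scale in experiment 1, negative without uninduced library 3 alone, and from -0.14 to -0.033 in experiment 2.

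Signs turned only for values that were not called. RBFOX2 in experiment 1 was -0.0013 in DESeq2, -0.0014 with its size factors in edgeR, -0.019 with library totals, -0.0049 with a mean of at least 50 reads and -0.036 to 0.063 with 1 library left out. With 1 library left out, the CDYL circRNA of experiment 1 ran from -0.28 to 0.11, the MAN1A2 circRNA from -0.097 to 0.16 and RBFOX3 of experiment 2 from -0.18 to 0.076. Apart from the changes in what was tested, the causes were not tested. Depth limits which circRNAs could be tested, as 1701 of 29693 passed the count minimum in experiment 1. Of simulated 4-fold circRNA changes, 66.3% were recovered in experiment 1 and 30.9% in experiment 2, whose libraries held 10004 to 22661 and 18945 to 28691 back-splice reads, so total depth alone does not account for the recovery. Counts of linear junctions were not run, since the tables hold none, and neither was the motif search.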

Other observations

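The tests in this part were chosen after the result was seen. The circRNAs of this paragraph were called in experiment 2 and, beyond those named by the rule, chosen after their values were seen. The circRNA of the atypical cadherin gene FAT1 (chromosome 4, 187627717 to 187630999) had 210 reads in parental and 49 in induced cells (log2 -1.82), that of FBXW7, a substrate adaptor of a ubiquitin ligase, 141 against 27 (-2.12), that of the nucleosome remodeller gene SMARCA5 196 against 62 (-1.38), that of FOXK2 199 against 46 (-1.85) and that of the nuclear export receptor gene XPO1 78 against 17 (-1.92). The circRNA of the centrosomal gene CCDC18 had 87 against 247 reads (1.79), those of MAN1A2 ending at 117963271 and 117984947 had 232 against 364 (0.93) and 83 against 159 (1.20), and those of DNAH14 had 243 against 389 (0.93) and 154 against 260 (1.03). The log2 fold changes of their host genes were -0.93 for FAT1, -0.66 for FBXW7, -0.95 for SMARCA5, -0.17 for FOXK2, -0.34 for XPO1, 0.21 for CCDC18, 0.28 for MAN1A2 and 0.81 for DNAH14. None of these circRNAs was called against its host by edgeR, a test that recovered 6.15% of simulated 4-fold changes. Of the 39 called circRNAs with a host in the test, 1 had its host called in the opposite direction, that of TCFL5 (-2.72 against 0.52).

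Some of the genes silent in the inducible line are neighbours. Along 12101 genes with at least 150 reads over the parental libraries, 161 kept at most 5% of them in the induced cells of experiment 2, and 6 of these are consecutive on the X chromosome: GYG2, ARSE, PRKX, PUDP, STS and PNPLA4. SHROOM2 and WWC3, also silent, lie beyond ANOS1, with 1134 reads in parental and 4505 in induced cells, and TBL1X, with 3301 and 3146. Next to them lie CLCN4, with 1052 reads in parental and 88 in induced cells, and MID1, whose circRNAs fell, with 47778 and 8520. On the other side of the run, AKAP17A, DHRSX, ZBED1 and CD99 had 9163, 1738, 2376 and 19368 reads in parental and 6543, 1287, 2482 and 8722 in induced cells. A chance arrangement of the silent genes is argued against, as the longest run in 10000 random arrangements was 4 (permutation p = 1e-04, the smallest possible). So is a rise of RBFOX1 above its uninduced level, since the uninduced cells of experiment 1 held 0.037% of the parental level over GYG2 and PRKX, the 2 of the 6 genes that its table lists. Those uninduced cells held 3.77 CPM of RBFOX1, against 0 in parental cells, so an effect of that lower level stays open. A loss of this segment in the clone may account for it, but loss and silencing cannot be told apart from read counts, in which the highest share kept by a gene of the run was 0.208%.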
